A study of Mus musculus with 6 samples.

How the data were processed

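Transcript levels were measured in 6 samples of mouse bone marrow cells, 3 from wild-type animals (WT) and 3 lacking Spred1 (KO), each on its own 1-colour array labelled with Cy3. The sorted cells were negative for lineage markers and CD48 and positive for c-Kit and Sca-1, a gate that enriches for haematopoietic stem cells and early progenitors. RNA was isolated from cells sorted straight into a lysis reagent and labelled with a kit for low RNA input, per the labels' protocols. The labels number the samples 1 to 3 within each genotype and do not say whether they came from separate animals. The p-values below therefore measure the spread between these samples, which may in part be technical.

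Spots were read with Agilent Feature Extraction 10.7.3.1, per the file headers. The value used for each spot was the processed signal, an intensity on a linear scale that had been corrected for background and for spatial and multiplicative trends within the array, with surrogate values for spots near background, per the file headers. The headers name no step between arrays. The authors' deposited value table held the same intensity divided by 1 constant per array, between 304 and 368, which lay close to the 75th percentile over all 62976 spots of the array. That table was on a linear scale and was not centred on genes, as its comparison with the scanner values showed. Its medians ran from 0.0638 to 0.075. It served as an alternative.

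Each array held 59305 spots other than controls, which made 55681 probes under 34650 gene names. Control spots were left out, as were the 92 to 155 spots per array that the scanner software had marked as outliers. No spot was saturated. Spots of 1 probe were averaged. Values were log2 intensities minus the 75th percentile of the array, so that a value of 0 means a signal equal to that percentile. For a gene name with several probes, the probe with the highest mean over all 6 arrays was used. Features were kept where the scanner software called them well above background on all 3 arrays of at least 1 genotype, which left 19611. Gene names are those of the array's design. The accessions of 28026 probes were found in a table of current symbols, and 1651 of these carry another symbol there. Positions are those given in the scanner files, on mouse genome build mm9.

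Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), as KO minus WT and without further covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Errors of differences are standard errors (SE) of that fit. The fit was tested on simulated data with the measured means of 19606 genes and 3 arrays per genotype. The spreads were the measured ones after limma had drawn them towards a common value. They therefore varied less between genes than the measured spreads. Noise was independent between genes, and 50 genes were changed at each of 4 folds. The fit recovered 34% of genes changed by 1.5-fold, 80% of those changed by 2-fold, and 100% of those changed by 4-fold or 8-fold, with 8 false calls among 165. With so many calls the adjusted threshold is looser than in the measured data, which gave 4 calls. These shares therefore do not carry over to the measured data, where the smallest change that passed was 3.95-fold. Where a gene was not well above background on any array of 1 genotype, its difference is given as a bound. The bound sets the mean of the brighter genotype against, on each array of the dimmer one, the higher of the probe's own signal and the lowest signal among probes well above background.

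Before the data were examined, 33 gene lists covering pathways, cell states, processes, the sorting gate, other cell types and sex-linked genes were fixed, and 32 had the 5 measured members required for a test. Each was tested against all other genes with limma's camera at a preset correlation between genes of 0.01. The same test with the correlation estimated from the residuals, and limma's fry, were run beside it. Members were counted over all genes and adjusted over the list alone. Genes within 10 Mb of Spred1 were compared with all others by Fisher's exact test, two-sided, as planned before the data were examined. The same comparison at an unadjusted p under 0.001 was added after the data had been seen.

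The genes named in the text follow a rule fixed before the data were examined. It takes the Spred family, the genes that pass filled up to 10 per direction with those of smallest p that have a symbol, a difference of at least 1.5-fold and no overlap between the genotypes, up to 4 members of each list that passes, 3 members of 5 lists whatever their result, the gate genes, and the brightest members of the lists of other cell types. Genes near Spred1 outside this rule were named after their values had been seen. The text prints some of the genes this rule names, and 1 list and 1 gene are not reported here.

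The arrays lay on 2 slides that were also scanned apart. Slide 1 held replicates 1 and 2 of each genotype and slide 2 held replicate 3 of each. Arrays of the same replicate number also shared a row of the slide. WT arrays always lay in position column 2 of the slide and KO arrays in column 4, so that position and genotype cannot be told apart. Alternatives covered the replicate number and the slide as blocks, each slide alone, background correction with normexp (offset 50) followed by quantile normalization, quantile normalization, median centring, the authors' table, the filter on dim probes, the handling of several probes per gene, the prior variance, array weights, the threshold, the window around Spred1, and leaving out each array. The number of arrays limits the precision, and the share of spots well above background, from 52.3% to 53.4% per array, sets which genes could be measured.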

Results

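Bone marrow cells of the CD48-negative, lineage-negative, c-Kit-positive and Sca-1-positive gate were profiled from wild-type mice (WT, 3 arrays) and mice lacking Spred1 (KO, 3 arrays), all labelled as strain C57BL/6. Spred1 encodes an inhibitor of Ras-ERK signalling, the kinase cascade that relays growth factor signals. The comparison asks which transcripts of these stem and progenitor cells differ when Spred1 is lost. Pearson correlations across features, which are not independent replicates, lay between 0.988 and 0.995 for all pairs of arrays. Between genotypes, 96.6% of the 19611 features differed by less than 1.5-fold. The typical spread between arrays of a genotype was 0.14 on the log2 scale (median SD).

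The targeted gene was represented by 3 probes, which moved apart. The probe at chromosome 2, 116998491 to 116998550, annotated to transcript variant 2, was 5.44-fold brighter in KO than in WT (log2 difference 2.44 ± 0.16 SE, limma adjusted p = 0.012 over 27809 probes). A probe at 117005906 to 117005965, annotated to transcript variant 1, stood at 50.7% of the WT signal in KO (log2 difference -0.98 ± 0.09 SE, limma adjusted p = 0.0591 over the same probes). The probe tested for the gene, with the highest mean over the 6 arrays, lies at 117004952 to 117005011 and is also annotated to variant 1. It differed by -0.14 ± 0.09 SE (limma adjusted p = 0.554 over all genes). All 3 KO arrays lay on one side of all 3 WT arrays for the variant 2 probe and for the variant 1 probe at 117005906. The exact two-sided permutation p was 0.1 for each, the smallest that 3 against 3 arrays allow, and 0.3 for the tested probe. The deleted part of the gene is not given in the sources used here, so a probe may lie outside it and none of them checks the labels.

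Of the relatives of Spred1, Spred2 measured 0.49 ± 0.15 SE higher on the log2 scale in KO and did not pass (limma adjusted p = 0.366), and Spred3 was not well above background on any array.

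**Figure D1:**
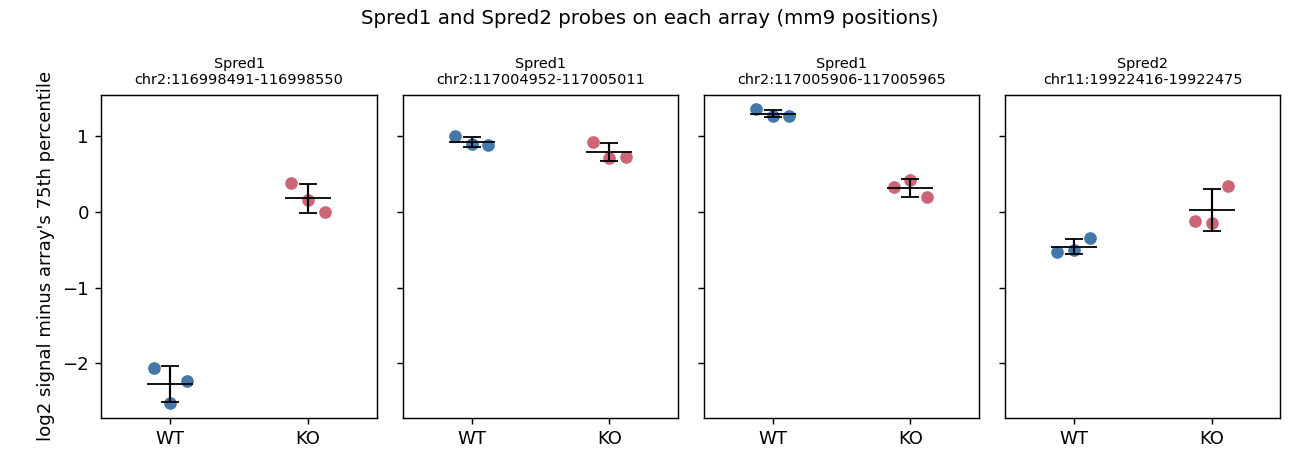
Signal of the 3 Spred1 probes and the Spred2 probe on each array, as log2 signal minus the 75th percentile of the array on the vertical axis, by genotype on the horizontal axis. Points are arrays, and bars are the mean and SD of 3 arrays; the Spred1 probe at 116998491 lies higher on every KO array and the one at 117005906 lower.

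Few single genes separated the genotypes. Transcripts of 2 genes rose in KO and those of 2 fell, out of 19611 tested with limma. The predicted transcript F830208F22Rik on chromosome 18 rose 4.53-fold (log2 difference 2.18 ± 0.11 SE, adjusted p = 0.0077). The RIKEN clone A930030B08Rik on chromosome 7 was not well above background in WT and rose at least 2.62-fold (adjusted p = 0.0456). Jmjd7, a gene of the jumonji-domain family on chromosome 2, fell by 3.84 ± 0.30 SE on the log2 scale (adjusted p = 0.0456) and was well above background on 1 of 3 KO arrays. The long non-coding RNA Gm14207 on the same chromosome, not well above background in KO, fell at least 4.59-fold (adjusted p = 0.0456). With each array left out in turn, the F830208F22Rik call was lost only without KO replicate 2 (adjusted p = 0.0817). The Jmjd7 call held only without KO replicate 3, the Gm14207 call only without KO replicate 1, and the A930030B08Rik call in none of these fits. With the slide as a block, 2 genes were higher and 1 was lower. With the replicate number as a block, 0 were higher and 0 lower, and within slide 1, with 2 arrays per genotype, none passed.

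Below the threshold, 2390 features had an unadjusted limma p under 0.05, where chance gives 981 on average, with 1410 of them higher and 980 lower in KO. Splits of the 6 arrays into 3 and 3 that mix the genotypes gave 394 to 2222 such features. Counts above 981 thus arose without the genotype grouping too. Over the arrays left out in turn the counts between genotypes ran from 876 to 1770 higher and from 522 to 1277 lower, both lowest without KO replicate 3. The number of genes lower in KO at unadjusted p under 0.05 was 553 without WT replicate 1. The 3 arrays of one genotype lay wholly above or below those of the other for 3810 features, 19.4% of all, against 10% by chance. Among named genes that did not pass, the GTP-binding protein gene Gem measured 0.87 ± 0.08 SE higher in KO (adjusted p = 0.0637) and the chemokine gene Ccl5 1.60 ± 0.17 SE higher (adjusted p = 0.0848). Further genes with higher values were Etv1, Sema3d, Gabra2, Adamts14, Speer1-ps1 and Rasgef1c, with adjusted p of 0.132 to 0.215. Their differences were 0.64 to 1.27, and Adamts14, not well above background in WT, was at least 2.13-fold higher. Genes with lower values were the RNA-binding protein gene Rbpms2 (-1.32 ± 0.15 SE, adjusted p = 0.123) and the chromatin remodeller gene Ino80, whose other probe measured 0.12 ± 0.098 SE. The transglutaminase gene Tgm5 was not well above background in KO and at least 4.2-fold lower there. Rgs7bp, Plod1, Pyroxd2, Wdr65 and Lhx1 had lower values too. Lhx1 was not well above background in KO either, and its bound was only 1.39-fold (adjusted p = 0.287).

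Genes that differed were concentrated beside Spred1 on chromosome 2. Within 10 Mb of Spred1, 2 of 154 measured genes passed the adjusted threshold, Jmjd7 and Gm14207, against 2 of 19312 elsewhere (odds ratio 127, 95% interval 9.12 to 1747, Fisher's exact p = 3.7e-04, two-sided). At an unadjusted limma p under 0.001, a threshold added after the data had been seen, 10 of the 154 genes counted against 47 of the 19312 (odds ratio 28.4, 95% interval 12.6 to 58.5, Fisher's exact p = 2.2e-11). Of these 10 genes, 8 had lower signal in KO. Besides Jmjd7, Gm14207, Tgm5 and Ino80 they were the mitochondrial dehydrogenase gene Ivd (-0.58 ± 0.09 SE), the non-coding RNA 1700054M17Rik (-1.43 ± 0.19 SE, well above background on 1 of 3 KO arrays), the transcript ENSMUST00000180041 (-0.96 ± 0.16 SE) and an unnamed transcript whose probe lies beside that of Gm14207 and is not independent of it. These genes, other than those the naming rule gives, were chosen after their values were seen. The sulfotransferase gene Chst14 (0.81 ± 0.13 SE) and the exonuclease-domain gene Exd1 (1.62 ± 0.26 SE) had higher signal in KO. All 10 lay between 1.13 and 3.87 Mb from Spred1 towards higher coordinates, where most measured genes lie: within 5 Mb they were 10 of 89 genes on that side and 0 of 21 on the other (Fisher's exact p = 0.204, two-sided). No gene of the region passed the adjusted threshold without WT replicate 1, without WT replicate 2, without KO replicate 2, under quantile normalization or among genes well above background on all 6 arrays. At p under 0.001, 6 to 11 genes of the region counted over the arrays left out in turn, past Fisher's exact test each time, and 9 with the slide as a block and 8 within slide 1. The 6 genes arose without KO replicates 1, 2 or 3.

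**Figure D2:**
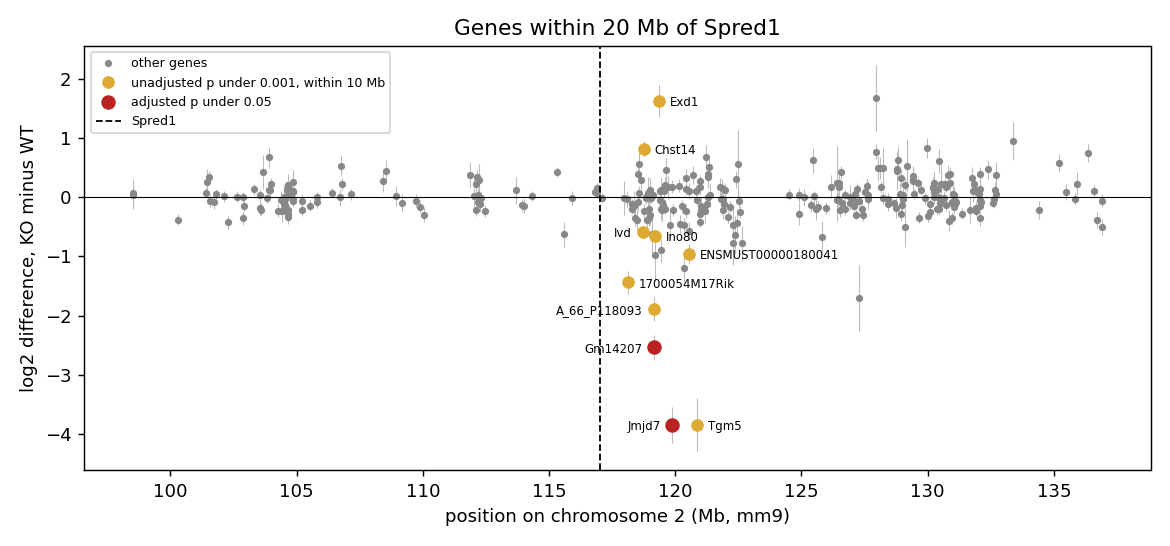
Log2 difference (KO minus WT, vertical axis, with SE bars) of each measured gene within 20 Mb of Spred1 against its position on chromosome 2 in Mb (mm9, horizontal axis). Red points passed the adjusted threshold, and yellow points are the other genes within 10 Mb at an unadjusted p under 0.001; all 10 lie to the right of Spred1 (dashed line), where 89 of the measured genes within 5 Mb lie against 21 to the left.

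Of the 32 gene lists tested, 12 passed the threshold with camera at the preset correlation, 7 lower and 5 higher in KO. None of the 12 passed when the correlation between genes was estimated from the residuals, where limma adjusted p lay between 0.647 and 0.708, and no member of any list passed over all genes. With limma's fry, 0 lists passed the directional test and 5 the mixed test. The 12 lists compare with 17 for the highest of the other splits of the 6 arrays into 3 and 3.

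Genes of cholesterol synthesis, heat shock and the unfolded protein response were lower in KO, with the smallest p of the 32 lists by camera at the preset correlation. With an estimated correlation and by directional fry, glycolysis genes had the smallest p instead (adjusted p = 0.647 and 0.236). All 23 measured genes of cholesterol synthesis had lower values in KO (mean log2 difference -0.37, camera adjusted p = 2.2e-05; adjusted p = 0.647 with an estimated correlation). Examples were Sqle (-0.68 ± 0.28 SE), which encodes an oxygenase of sterol synthesis, Mvd (-0.61 ± 0.21 SE), Lss (-0.56 ± 0.20 SE) and Nsdhl (-0.50 ± 0.16 SE). Of these 23 genes, 0 fell over all genes, 0 fell adjusted over the list alone, and 5 were lower at an unadjusted p under 0.05. The shift was -0.20 within slide 1 and -0.70 within slide 2, and -0.17 without KO replicate 3, where Sqle measured -0.37 and Lss -0.35.

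Heat shock genes, the chaperones induced by protein damage, shifted by a mean of -0.50 and a median of -0.25 (14 measured, 12 with lower values, camera adjusted p = 1.0e-04; adjusted p = 0.647 with an estimated correlation). None fell over all genes, 4 fell adjusted over the list alone, and 6 were lower at an unadjusted p under 0.05. The inducible chaperone gene Hspa1a was well above background on 3 WT arrays and on 0 KO arrays, and fell at least 2.84-fold; the others were Hsph1 (-1.0 ± 0.24 SE), Dnaja1 (-0.70 ± 0.20 SE) and Hsp90aa1 (-0.40 ± 0.11 SE). Genes of the unfolded protein response, which serves folding in the endoplasmic reticulum, shifted by a mean of -0.27 (21 measured, 19 with lower values, camera adjusted p = 1.0e-04; adjusted p = 0.647 with an estimated correlation), among them Hspa5 (-0.42 ± 0.11 SE) and Pdia6 (-0.39 ± 0.14 SE). None fell over all genes or adjusted over the list alone, and 5 were lower at an unadjusted p under 0.05. Heat shock genes shifted by -0.45 and -0.60 within slides 1 and 2, and unfolded protein response genes by -0.22 and -0.38. Among the 13 heat shock genes well above background on all 6 arrays, which leaves out Hspa1a, the mean was -0.33 and kept its camera call.

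Genes of DNA replication (mean -0.16, 31 measured, camera adjusted p = 0.00269), oxidative phosphorylation (-0.084, 40 measured, 0.00637), glycolysis (-0.099, 19 measured, 0.0309) and the immediate early response (-0.29, 23 measured, 0.0134) were also lower in KO as lists. None of their members passed over all genes or adjusted over the list alone, and 2, 1, 2 and 2 of them were lower at an unadjusted p under 0.05. With an estimated correlation their adjusted p were 0.707, 0.707, 0.647 and 0.708. Examples were Rfc3 (-0.37 ± 0.13 SE), Cycs (-0.34 ± 0.12 SE), Pfkl (-0.39 ± 0.12 SE) and Dusp2 (-0.30 ± 0.08 SE). Within slides 1 and 2 the means were -0.058 and -0.36 for DNA replication genes, -0.0071 and -0.24 for oxidative phosphorylation genes, -0.074 and -0.15 for glycolysis genes, and -0.45 and 0.025 for immediate early genes. Within slide 1 the calls of DNA replication, oxidative phosphorylation and glycolysis genes ended (camera adjusted p = 0.284, 0.572 and 0.114). Relative to the WT mean, the median DNA replication gene was lowest on a WT array, replicate 2 (-0.30), below every KO array (-0.16 to -0.099). The DNA replication call ended without WT replicate 3 (-0.061), and that of oxidative phosphorylation genes without WT replicate 3 (-0.019) or KO replicate 2 (-0.056). The glycolysis call ended without WT replicate 2 (-0.097), WT replicate 3 (-0.090), KO replicate 1 (-0.092) or KO replicate 3 (-0.083). The immediate early call ended without WT replicate 2 (-0.11) or KO replicate 1 (0.0060). Without a change of call, the mean of DNA replication genes moved to -0.10 without WT replicate 1 and to -0.31 without WT replicate 2, and that of immediate early genes to -0.44 without WT replicate 3 and to -0.58 without KO replicate 2.

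Feedback and target genes of ERK signalling were higher in KO as a list (mean 0.20, 16 measured, 11 with higher values, camera adjusted p = 0.0257; adjusted p = 0.647 with an estimated correlation). None rose over all genes and 3 rose adjusted over the list alone: the transcription factor genes Etv1 (1.27 ± 0.18 SE) and Etv5 (0.69 ± 0.13 SE), and the cytokine gene Lif (1.13 ± 0.29 SE), which was well above background on 1 WT array and 3 KO arrays. The other 13 did not pass, and 4 of the 16 were higher at an unadjusted p under 0.05. The mean was 0.099 within slide 1 and 0.40 within slide 2, and the call ended within slide 1 (adjusted p = 0.103) and without WT replicate 3 (0.088) or KO replicate 2 (0.099). Genes of the Ras-MAPK pathway itself did not pass as a list (mean -0.062, camera adjusted p = 0.177).

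Multipotent progenitor genes were higher in KO as a list (mean 0.35, 13 measured, 12 with higher values, camera adjusted p = 0.0134; adjusted p = 0.647 with an estimated correlation), with 0 members passed over all genes or adjusted over the list alone and 3 higher at an unadjusted p under 0.05. Examples were the chromatin organiser gene Satb1 (0.46 ± 0.12 SE), the receptor gene Notch1 (0.66 ± 0.19 SE) and the cytokine receptor gene Flt3 (0.42 ± 0.13 SE). Without WT replicate 1 the mean was 0.081 and the call ended (adjusted p = 0.232), as it did without KO replicate 3 (0.24). Within slides 1 and 2 the means were 0.33 and 0.37, and the call ended within slide 1 (adjusted p = 0.158). Haematopoietic stem cell genes did not pass as a list (mean -0.082, 30 measured, 21 with lower values, camera adjusted p = 0.0967), with Ifitm1 at -0.35 ± 0.08 SE, Esam at -0.43 ± 0.12 SE and Slamf1 at -0.56 ± 0.22 SE. Slamf1 overlapped between the genotypes and measured -0.34 without KO replicate 1.

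Among markers of other cell types, the monocyte and macrophage list (mean 0.29, 19 measured, camera adjusted p = 0.044; adjusted p = 0.707 with an estimated correlation) and the dendritic cell list (mean 0.12, 9 measured, camera adjusted p = 0.044; adjusted p = 0.647 with an estimated correlation) were higher in KO. None of their members passed over all genes or adjusted over the list alone, and 1 and 2 were higher at an unadjusted p under 0.05. WT replicate 1 stood apart, most of all in myeloid transcripts. The median neutrophil marker lay at -1.60 on it, relative to the WT mean, against 0.85 and 0.74 on the other WT arrays and 0.12 to 0.46 on the KO arrays. WT replicate 1 was also the lowest array in B cell (-0.36), erythroid (-0.27) and T and NK cell markers (-0.13), but not in dendritic cell or megakaryocyte markers. On the first principal component of all features (36% of variance) it lay at -36. The other WT arrays lay at -6.4 and -5.5 and the KO arrays at 4.6 to 23. Every WT array thus lay below every KO array on that component. Without WT replicate 1 the monocyte and macrophage mean was 0.017 (adjusted p = 0.805), without KO replicate 2 it was 0.17 (adjusted p = 0.423), and without WT replicate 3 it was 0.45. It was 0.18 under normexp with quantile normalization. The mean was 0.47 within slide 1 and -0.077 within slide 2. The dendritic cell call ended without WT replicate 2 (0.061), KO replicate 1 (0.035) or KO replicate 3 (0.10), and the mean was 0.21 without KO replicate 2, with means of 0.14 and 0.069 within slides 1 and 2. That call also ended within slide 1 (adjusted p = 0.103), and the mean was 0.18 among genes well above background on all 6 arrays. Ribosomal protein genes were higher in KO as a list (mean 0.093, 43 measured, camera adjusted p = 6.3e-04; adjusted p = 0.707 with an estimated correlation), a direction that turned under quantile normalization (-0.018) and under normexp with quantile normalization (-0.020). None of its members passed over all genes or adjusted over the list alone, 1 was higher at an unadjusted p under 0.05, and the mean was 0.052 without WT replicate 1, 0.12 within slide 1 and 0.040 within slide 2. Without the filter on dim probes the calls of ERK feedback genes, multipotent progenitor genes, monocyte and macrophage markers and dendritic cell markers ended (adjusted p = 0.106, 0.0618, 0.194 and 0.258). With array weights those of ERK feedback genes (0.0668) and monocyte and macrophage markers (0.128) ended, the latter also with quantile normalization (0.0538).

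**Figure D3:**
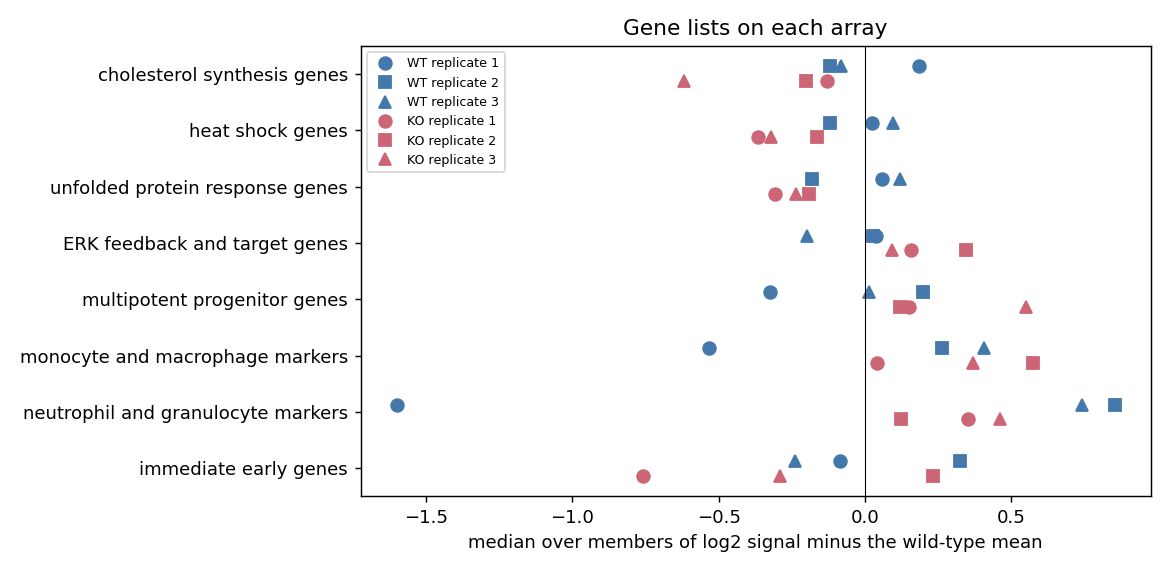
Median over the members of 8 gene lists of the log2 signal minus the WT mean of each gene (horizontal axis), on each array; colours mark genotypes and symbols mark replicate numbers. Heat shock, unfolded protein response and cholesterol synthesis genes lie lower on every KO array than on every WT array, by narrow margins. The lowest WT array (replicate 2) and the highest KO array lie at -0.118 and -0.164 for heat shock genes. They lie at -0.182 and -0.191 for unfolded protein response genes, and at -0.119 and -0.131 for cholesterol synthesis genes. ERK feedback genes lie higher on every KO array, with the highest WT array at 0.039 and the lowest KO array at 0.092. The medians of glycolysis genes, niche adhesion genes, and stromal and endothelial markers, not drawn here, did not overlap between genotypes either. WT replicate 1 lies lowest in neutrophil markers, at -1.60.

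The genes that define the gate did not separate the genotypes. Kit differed by -0.088 ± 0.12 SE (limma adjusted p = 0.765), Ly6a, which encodes Sca-1, by 0.078 ± 0.17 SE (0.859), and Cd48 by 0.12 ± 0.23 SE (0.836). Transcripts of other lineages were present in both genotypes although the gate excludes their surface markers. The log2 signal of the neutrophil gene S100a9 was 7.46 ± 1.32 (SD, n = 3) in WT and 7.91 ± 0.17 (SD, n = 3) in KO, that of the erythroid gene Hbb-bt was 6.34 ± 0.38 and 6.75 ± 0.54, and that of Siglech, a marker of plasmacytoid dendritic cells, was 7.37 ± 0.11 and 7.66 ± 0.10.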

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

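For 71 of the genes the naming rule gives, some of which the text does not print, 1269 values were recomputed. Of these, 1195 kept direction and side of the threshold, 35 lost their call, 10 gained one, 0 reversed and 29, without a test, moved by over 1 SD. Only the 4 genes that passed in the main fit had a call to lose. Most of the 1195 values therefore belong to genes that stayed below the threshold, and their share does not measure how stable the calls are. The counts of genes higher and lower in KO were 2 and 2. They became 5 and 4 with normexp and quantile normalization, 1 and 0 with quantile normalization, 1 and 0 among genes well above background on all 6 arrays, and 6 and 6 with a trended and robust prior. Without the filter on dim probes they were 0 and 0, at an adjusted p under 0.1 they were 5 and 4, and without genes within 20 Mb of Spred1, an alternative chosen after seeing the data, they were 1 and 0. With every probe tested, 6 of 27809 probes were higher, a count of probes and not of genes that includes the variant 2 probe of Spred1. With slide as a block 1 gene was lower. Within slide 1, where each genotype has 2 arrays, 0 and 0 passed. Arrays of the same replicate number shared a slide and a row of it. Their residuals correlated at -0.025, 0.15 and 0.071, against -0.23 to 0.18 for the other pairs of a WT and a KO array. These values do not settle whether the numbers pair the arrays. With the replicate block 0 genes were higher, 0 were lower and 12 lists passed. Leaving out each array in turn gave 0 to 2 higher, 0 to 3 lower, 0 to 2 passing genes near Spred1, and 9 to 14 lists. The count of genes near Spred1, 2 in the main setting, was 0 (Fisher's exact p = 1) with quantile normalization and among genes well above background on all 6 arrays. It rose to 5 with a trended and robust prior, and to 3 with normexp and quantile normalization or with the mean of all probes of a gene. With every probe tested, 4 probes near Spred1 passed, and the count of genes was not taken. With slide as a block the count of genes near Spred1 was 1. It was not computed where no gene passed at all: within slide 1, with the replicate block, without the filter on dim probes and without KO replicate 2. The Spred1 level at the tested probe, -0.14, ran from -0.21 to -0.10 over the arrays left out and did not pass in any setting that tested it. It was not computed with every probe tested or with the mean of all probes of a gene. Over all probes, the variant 2 probe of Spred1 passed (log2 difference 2.44, limma adjusted p = 0.012). Gene lists past the threshold, 12, fell to 7 within slide 1, to 0 with camera at an estimated correlation, to 0 with directional fry and to 5 with mixed fry. Heat shock, unfolded protein response and cholesterol synthesis genes passed in every camera setting at the preset correlation. Cytosolic ribosomal proteins reversed to -0.020 with normexp and quantile normalization and to -0.018 with quantile normalization. Immediate early genes ran from -0.58 without KO replicate 2 to 0.0060 without KO replicate 1, where they reversed, as they did within slide 2 (0.025), and so did monocyte and macrophage markers there (-0.077). The filter on dim probes changes the number of genes tested, and slide 1 alone leaves fewer arrays; for the other changes the cause was not tested. No scaling moved the median of all genes by as much as 0.1.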

Other observations

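The tests of the region beside Spred1, of heat shock genes and of the myeloid lists were worded after the results had been seen, except Fisher's test of the adjusted calls near Spred1, planned before the data were examined, and the counts over other splits of the arrays for genes and lists, worded before those splits were computed. Other groups showed values without passing. Ccl5 rose adjusted over the list alone among 23 NF-kB and cytokine genes (1.60 ± 0.17 SE), and the erythroid blood group gene Rhag, chosen after its values were seen, among 16 erythroid markers. Rhag was not well above background in WT and at least 1.69-fold higher in KO. Neither list passed (camera adjusted p = 0.982 and 0.15).

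Other lists did not pass with camera either: interferon response genes (adjusted p = 0.982), p53 targets (0.173), mitosis genes (0.847), quiescence regulators (0.312), TGF-beta and BMP targets (0.0967) and Wnt and Notch targets (0.723). The same held for fatty acid oxidation genes (0.532), niche adhesion genes (0.346) and sorting gate genes (0.326). Among markers of other cell types, those of T and NK cells (0.055), B cells (0.0967), neutrophils (0.18), megakaryocytes (0.365), mast cells and basophils (0.982) and stroma and endothelium (0.232) did not pass. The sex-linked list had 3 measured genes and was not tested. The median, the mean and camera's direction differed in sign for interferon response genes (-0.033, 0.018, lower), fatty acid oxidation genes (-0.033, 0.020, lower), and NF-kB and cytokine genes (-0.036, 0.041, higher). With limma's mixed fry test, T and NK cell markers (adjusted p = 0.00439), ERK feedback genes (0.00623), NF-kB genes (0.0363), p53 targets (0.0396) and heat shock genes (0.0396) passed. Ccl5 belongs to both the T and NK cell list and the NF-kB list, so these 2 calls are not separate. Of the 10 measured T and NK cell markers, only Ccl5 had an unadjusted limma p under 0.05.

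Of 291 windows of 10 Mb, the one on chromosome 2 from 110 to 120 Mb had 8 of 74 genes at an unadjusted limma p under 0.001. Next came 3 of 119 from 120 to 130 Mb and 3 of 184 from 150 to 160 Mb on that chromosome, and 3 of 26 on chromosome 5 from 10 to 20 Mb. The last were Speer1-ps1, 4933402N22Rik, chosen after its values were seen, and Sema3d, all with higher values in KO.

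The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The numbers of splits as large given here include the genotype split itself. The genotypes gave 4 genes past the threshold and the highest other split 0, a count reached by 1 split of 10. At an unadjusted p under 0.05 the genotypes gave 2390 features and the highest other split 2222, again with 1 split as large. The genotypes gave 12 lists and the highest other split 17, with 3 splits as large. For genes within 10 Mb of Spred1 at p under 0.001 the genotypes gave 10 and the highest other split 1, with 1 split as large. For genes elsewhere at that threshold the genotypes gave 47 and the highest other split 65.

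Genes beside Spred1 differed more often than others. Weaker binding of probes to DNA of another strain lowers signal, so the 2 genes with higher values in KO argue against it there, but it stays open for the lower genes, where 2 of 8 have a further probe above background and 1 of these was also lower. An action of Spred1 on its nearest neighbours stays open too: 0 of 5 genes within 1 Mb counted against 10 of 105 between 1 and 5 Mb, too few for a difference (Fisher's exact p = 1). A candidate explanation is that DNA of another strain, kept beside the knockout allele through breeding, carries its own expression levels; it needs changed genes to crowd near Spred1, and the odds ratio was 127. An effect of the allele along the chromosome would give the same crowding and was not tested apart from it, so the calls of Jmjd7 and Gm14207 may not follow from loss of Spred1 protein.

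The median heat shock gene was lower on every KO array than on every WT array (exact two-sided permutation p = 0.1, the smallest possible). The closest arrays were WT replicate 2 (-0.12) and KO replicate 2 (-0.16), relative to the WT mean. Over 4 other scalings the heat shock shift closest to 0 was -0.35, and the camera call at the preset correlation was kept. Median centring and the authors' table only move each array by a constant and could hardly change that call. Quantile normalization (-0.51) and normexp with quantile normalization (-0.35) could, and they argue against the scaling between arrays as the cause. In the main scaling the call was lost with an estimated correlation (camera adjusted p = 0.647) and by directional fry (adjusted p = 0.236). A bias that follows signal is argued against too. Of 10000 random lists matched on signal, 0 had a mean as low, and the median of their means was 0.020. For the 13 members well above background on all 6 arrays (mean -0.33), 0 of 10000 were as low (lowest random mean -0.23). The list was taken up after its shift was seen, and the draws ignore correlation between genes. These counts therefore give no p-value for the shift. Handling of the cells before lysis may have differed between genotypes and cannot be excluded: immediate early genes, which respond to it, overlapped between genotypes (exact two-sided permutation p = 0.4 of their medians per array). A lower chaperone level in cells without Spred1 stays open as well and was not tested apart from handling.

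The higher monocyte and multipotent progenitor lists in KO, which share members such as Vcam1, Flt3, Mpo and Cd48 with other lists, may reflect 1 WT array low in myeloid transcripts. That array was also the lowest in B cell, erythroid and T and NK cell markers. Without WT replicate 1 the monocyte and macrophage mean moved from 0.29 to 0.017 and the multipotent progenitor mean from 0.35 to 0.081, and both calls ended. The 3 progenitor genes of smallest p depended on that array less. Notch1 moved from 0.66 to 0.45 without it, and Satb1 and Flt3 stayed at or above 0.38 and 0.32 whichever array was left out. The explanation therefore concerns the list means, not every member. A smaller difference between the genotypes in these cell states stays open.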
